A study of Mus musculus with 3 samples.

How the data were processed

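Runx1 ChIP-seq was deposited for 3 replicates of mouse spinal cord. Per the labels' protocols, cells came from dissociated cords of perfused mice, were fixed with formaldehyde in pools of 5 cords, and were digested with micrococcal nuclease and sonicated before chromatin from 10 cords was pooled for each immunoprecipitation. The labels give 3 replicates of 1 group but do not say how animals were shared between them. The p-values on regions and genes therefore describe these libraries and not variation between animals. The tissue field of replicate 3 holds the antibody description in place of the tissue, and its group was taken from its title.

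The submitters' processing notes name Trimmomatic 0.38, FastQC, Bowtie2, SAMtools 1.9, Picard 2.18.26, MACS2 2.1.2 and the mouse build GRCm38. Their parameters, and the control library used in peak calling, are not given in the sources used here. Regions were called separately for each replicate, per the deposited files. Each deposited peak list gives a score, a fold over background (a ratio), −log10 p and −log10 q for every summit, as the authors' peak caller wrote them. The lowest deposited −log10 q values were 2.01, 2.00 and 2.00 in replicates 1, 2 and 3. The authors' annotated tables hold the same regions with a class of location and an assigned gene. Starts count from 0 in the deposited lists and are given here from 1.

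Regions with several summits were counted once and given the fold of their strongest summit. All regions lay on chromosomes 1 to 19, X and Y. The deposited fold and −log10 p of each summit were solved for a whole-number pileup and a background level under a Poisson model. A solution within 0.001 in −log10 p was found for 100% of the summits of each replicate. The lowest background level divided by the narrowest region gave the relative depth. Depth was otherwise unknown, and the intervals cover counting error only.

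Overlap of at least 1 bp was compared with 10000 random placements on the same chromosome, within the span of its RefSeq genes, in one-sided permutation tests. Location was compared with 1000 placements. Median folds were compared by two-sided permutation tests with 100000 resamples, and correlations by 10000 permutations. The 17 gene lists, with 400 entries in all, were written before the data were examined. Each list was compared with 10000 random lists of coding genes drawn from the same 10 bins of gene length, two-sided, with Benjamini-Hochberg adjustment over lists. Coding gene symbols of the annotated tables matched the RefSeq table in 98.8%, 99.7% and 99.1% of cases. Shares have 95% Wilson intervals. Named genes were those of the 20 regions shared by all 3 replicates with the highest worst percentile of fold, the RUNX family genes Runx1, Runx2 and Runx3 with Cbfb, 4 opioid receptor genes, and up to 4 members of each list with regions in the most replicates. Some genes that this rule names are not reported here.

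Alternatives were stricter limits (q of 1e-05, fold of 5), overlap of 50% of the shorter or of both regions, summits within 200 bp, equal numbers of regions, shifts of 10 to 50 kb, other gene assignments, and leaving out each replicate. A planned test for the Runx motif at summits needs a genome sequence, which was not used here, and it was not run.

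The scripts were tested on simulated data. Known pileups were recovered in 100% of 2000 simulated summits. Of 20 simulated placements of replicate 1 against replicate 3 without planted overlap, 5% were called, and 100% of 20 with planted overlap were. Of 2000 random lists of 24 genes, 1.05% were called, and 100% of 2000 lists with regions planted in many genes were. For medians in replicate 1, 5.5% of 200 simulations without a difference and 100% of 200 with a planted log2 difference of 0.5 were called. The medians simulation split replicate 1 into groups of near-equal size, where its strength test compared 430 with 21 regions. The planted effects were strong, so the 100% values do not give the power for weaker ones. The work used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.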

Results

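Runx1 is a DNA-binding transcription factor of blood and myeloid cells, and the series title places it in microglia, the resident macrophages of the central nervous system, in the setting of opioid analgesia and withdrawal. Chromatin bound by Runx1 was measured by chromatin immunoprecipitation and sequencing (ChIP-seq) of spinal cord cells from male C57BL/6J mice aged 8 to 10 weeks. Each of the 3 replicates was an immunoprecipitation of about 10 µg of chromatin pooled from 10 spinal cords, with 9 µg of a rabbit polyclonal antibody. All 3 replicates belonged to 1 group, so the comparisons are between replicates and between classes of regions and genes. Read totals were not given in the sources used here. The background level implied by the deposited values put the relative depth of replicates 1, 2 and 3 at 1, 1.07 and 1.52.

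The replicates differed widely in how much of the genome was called. Replicate 1 had 451 regions, replicate 2 had 1641 and replicate 3 had 13194, which was 3.64 and 29.3 times the number in replicate 1. The regions were assigned to 330, 1131 and 6887 of 21883 coding genes, or 1.51%, 5.17% and 31.5%. Median widths were 335 bp, 425 bp and 470 bp, and the regions covered 172 kb, 891 kb and 8460 kb. The widest region of replicate 3 spanned 26649 bp on chromosome 6 (52208231 to 52234879, GRCm38) with 64 summits and was assigned to Hoxa10, a homeobox gene of axial patterning. The next widest regions of replicate 3 were assigned, in order, to Sox2 (21957 bp), Zeb2 (15033 bp), Mir124a-2 (13879 bp) and Bahcc1 (13282 bp). These genes and Hoxa10 were chosen for width after the values were seen. The authors' fold over background at the strongest summit of each region had a median of 4.86 in replicate 1, 4.01 in replicate 2 and 3.81 in replicate 3. These folds describe regions within a replicate's own list, and a single replicate carries no error of its own.

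**Figure D1:**
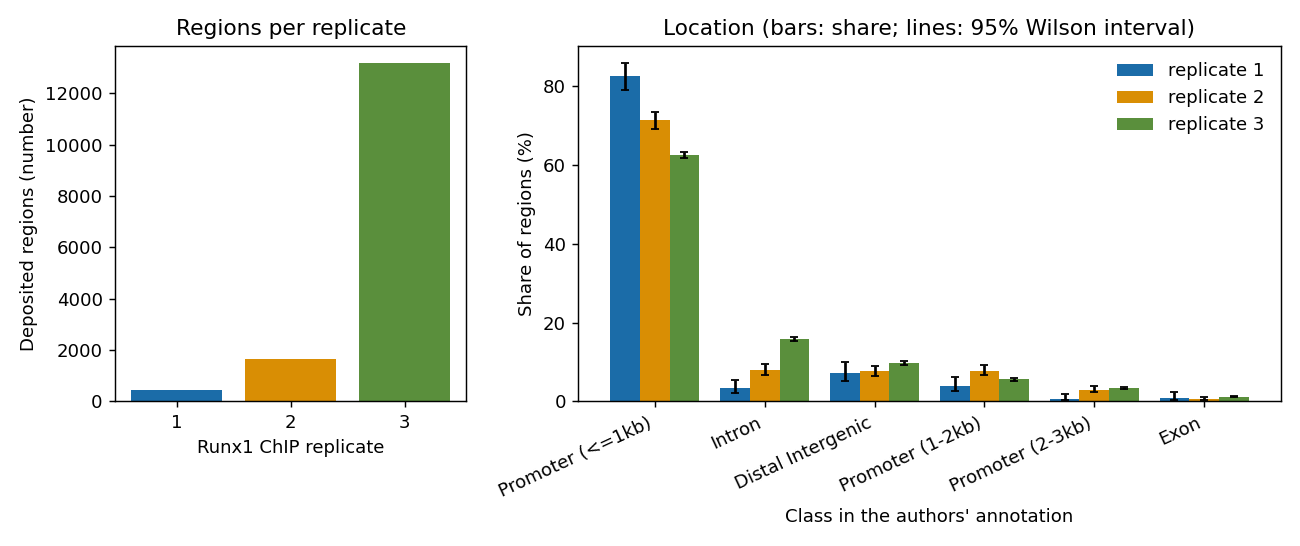
The left panel shows the number of deposited Runx1 ChIP regions in each replicate, and the right panel the share of regions (%) in the 6 most frequent classes of the authors' annotation, with 95% Wilson intervals. Replicate 3 had 13194 regions against 451 and 1641. The promoter class within 1 kb of a start site held 82.7%, 71.4% and 62.6% of the regions of replicates 1, 2 and 3.

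The strongest regions found in every replicate lay at promoters, several of them of lysosomal genes. The top region of all, by the lowest of its 3 within-replicate percentiles of fold, lay at the promoter of Amdhd2 (ENSMUSG00000036820), which encodes a deacetylase of amino sugar metabolism, on chromosome 17 (24163433 to 24164023 in replicate 1, GRCm38). Its fold was 36.8, 26.7 and 20.9 in replicates 1, 2 and 3, from summit pileups of 118, 97 and 306 fragments. Lamp1, a membrane glycoprotein of lysosomes, had a promoter region on chromosome 8 (13158897 to 13159372 in replicate 1) with folds of 15.7, 11.4 and 24.5. The lysosomal channel gene Mcoln1 had folds of 9.22, 8.03 and 10.4, the lysosomal transporter gene Mfsd1 12.1, 9.93 and 14.5, and Hexa, a subunit of beta-hexosaminidase, 11.3, 6.16 and 9.74. Ctsa, which encodes the lysosomal protease cathepsin A, had folds of 7.60, 7.57 and 9.44.

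Other genes assigned to the 20 top regions included B930059L03Rik, Zmym6, Ube2q1, Zbtb40, Gm26698, Pip4p1, Gm36967, Get4, Nudt9, Zbtb16, Pim3, Supv3l1 and Bhlhe40. Bhlhe40, a basic helix-loop-helix transcription factor, had folds of 7.56, 5.70 and 8.64 on chromosome 6 (108660078 to 108660523 in replicate 1). Zbtb16, which encodes a zinc-finger transcription factor, was the exception in position, with an intronic region on chromosome 9 (48737491 to 48737816 in replicate 1) and folds of 7.82, 5.97 and 11.3. All 20 regions had a fold of at least 5 in each of the 3 replicates.

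**Figure D2:**
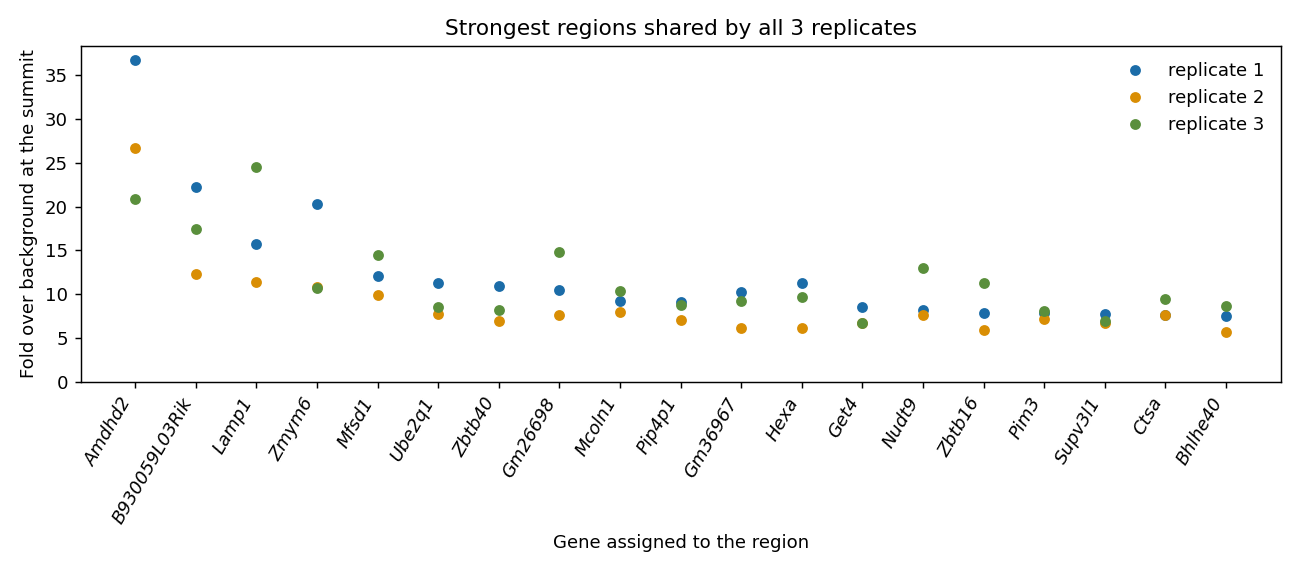
Each point is the fold over background (linear axis from 0) in 1 replicate at 1 of 19 of the 20 strongest regions shared by all 3 replicates, named by the authors' assigned gene. Amdhd2 had the highest fold in replicates 1 and 2 (36.8 and 26.7), and Lamp1 in replicate 3 (24.5).

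Regions of the smaller lists lay within those of the larger lists far more often than randomly placed regions. Of the 451 regions of replicate 1, 249 overlapped a region of replicate 2 by at least 1 bp (55.2%, 95% Wilson interval 50.6 to 59.7), against a mean of 0.286 by chance. Replicate 3 held 427 of the 451 regions of replicate 1 (94.7%, interval 92.2 to 96.4; chance mean 2.56) and 1512 of the 1641 regions of replicate 2 (92.1%, interval 90.7 to 93.3; chance mean 10.6). Each of the 3 pairs had a one-sided permutation p of 0.0001, the smallest that 10000 placements can give. With promoter regions placed at random gene ends, a test chosen after the data were seen, the chance means rose to 6.69 for replicates 1 and 2, 49.8 for replicates 1 and 3 and 163 for replicates 2 and 3. The permutation p stayed at 0.0001 for each. Gene ends here were starts and ends of all coding genes, so this placement cannot test overlap beyond a shared preference for promoters. The shares depended on the definition of overlap and on list length. Where at least 50% of both regions had to overlap, they were 34.1% for replicates 1 and 2, 32.6% for replicates 1 and 3 and 33.7% for replicates 2 and 3. Among the 451 regions of lowest q in each list, they were 30.6%, 28.2% and 45.5%. In the other direction, 3.11% of the regions of replicate 3 overlapped replicate 1 and 10.4% overlapped replicate 2. All 3 replicates shared 246 of the regions of replicate 1 (54.5%, interval 49.9 to 59.1; permutation p = 0.0001, the smallest possible). Only 21 regions of replicate 1 (4.66%) overlapped neither of the other lists.

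Shared regions of replicate 3 had higher folds than the rest of that list, and they were also wider. Median widths of shared and unshared regions were 869 and 438 bp in replicate 3, 440 and 329.5 bp in replicate 2, and 338 and 276 bp in replicate 1. Each fold was that of a region's strongest summit and the tests were not matched on width, so they do not separate strength from width. In replicate 3 the median fold was 5.33 over 1539 shared regions against 3.72 over 11655 unshared regions, a difference of 0.52 on the log2 scale (two-sided permutation p = 1e-05, the smallest that 100000 resamples can give). In replicate 2 the medians were 4.03 over 1515 shared and 3.82 over 126 unshared regions (permutation p = 0.0194). In replicate 1 they were 4.87 over 430 shared and 4.54 over 21 unshared regions, a difference that did not pass the test (permutation p = 0.234). Across shared regions, log2 fold correlated between replicates 1 and 2 (Pearson r = 0.573, Spearman rho = 0.435, 249 regions). The values were r = 0.324 and rho = 0.242 over 427 regions for replicates 1 and 3, and r = 0.341 and rho = 0.273 over 1512 regions for replicates 2 and 3. Each r and rho had a permutation p of 0.0001 before and after Benjamini-Hochberg adjustment, the smallest possible, and regions are not independent replicates. Without the 2 regions farthest from the median, r was 0.481, 0.277 and 0.326.

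Most regions lay at promoters. The authors' promoter class within 1 kb of a start site held 72.2% ± 10.1 (SD, n = 3) of the regions, with 82.7% in replicate 1, 71.4% in replicate 2 and 62.6% in replicate 3. Introns held 3.33%, 7.98% and 15.8%, and distal intergenic sequence 7.32%, 7.62% and 9.67%. Among the 246 regions shared by all 3 replicates, 206 (83.7%, 95% Wilson interval 78.6 to 87.8) were in the promoter class. Measured against RefSeq genes of the same build, 69.8%, 61.8% and 53.8% of the regions of replicates 1, 2 and 3 lay within 1 kb of a gene end, against 7.50%, 8.01% and 8.13% of random placements. The one-sided permutation p was 0.001 for each, the smallest that 1000 placements can give.

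Genes of myelinating cells and ribosomal protein genes carried regions in at least 2 replicates more often than random genes of matched length. A gene was counted if at least 2 replicates each had a region assigned to it, and the regions did not have to overlap. Of 23 oligodendrocyte list genes, 12 had such regions (52.2%, 95% Wilson interval 33.0 to 70.8) against 1.40 expected (permutation p = 0.0002, the smallest possible; adjusted p = 0.0034 over 17 lists). They included Cldn11, Cnp, Mbp, Mobp, Mog, Olig1 and Olig2. Mbp, which encodes myelin basic protein, had 5 regions in replicate 2 and 12 in replicate 3, the strongest on chromosome 18 (82553499 to 82560904 in replicate 3) with a fold of 12.99. Olig2, a transcription factor of the oligodendrocyte lineage, had folds of 5.53 and 9.01 at its strongest regions in replicates 2 and 3. These were different regions of chromosome 16 that did not overlap (91227650 to 91228486 and 91224842 to 91226868). Of 30 ribosomal protein genes, 6 had regions in at least 2 replicates (20.0%, interval 9.51 to 37.3) against 1.26 expected (permutation p = 0.0028, adjusted p = 0.0238), with Rps19 at folds of 5.26 and 8.66. Replicate 1 had a region at 0 of the 23 oligodendrocyte and 0 of the 30 ribosomal genes. Both counts therefore rest on replicates 2 and 3. Leaving out replicate 2 or 3 required a region in replicate 1, so neither list could exceed random lists there. Replicate 2 on its own had 12 oligodendrocyte genes (expected 1.33, adjusted permutation p = 0.0034). It also had 6 ribosomal genes (expected 1.26, adjusted permutation p = 0.0255). The ribosomal result did not pass without matching on gene length (6 genes against 1.63 expected, adjusted permutation p = 0.0578) or at a fold of 5 or more (1 gene against 0.265 expected, adjusted permutation p = 1). The ratios to expectation there were 3.68 and 3.78, against 4.77 with all regions and matching.

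Microglial genes did not stand out by this measure. Of 24 homeostatic microglial genes, 1 had regions in at least 2 replicates (4.17%, 95% Wilson interval 0.739 to 20.2) against 1.29 expected (permutation p = 1). That gene was Sall1, a zinc-finger transcription factor with a fold of 5.48 in replicate 2 and 11.02 in replicate 3. The list of microglial and macrophage transcription factors had 3 of 24 genes (Bhlhe41, Mef2a and Sall1; expected 1.55, adjusted permutation p = 0.965). Bhlhe41 had a promoter region in all 3 replicates, with folds of 5.04, 6.72 and 7.84. Microglial activation and phagocytosis had 2 of 26 genes, the cathepsin genes Ctsb and Ctsd (expected 1.44, adjusted permutation p = 1). Fewer homeostatic microglial than oligodendrocyte genes had regions in at least 2 replicates (Fisher's exact test, adjusted p = 0.00128 over 10 comparisons). That difference rests on replicates 2 and 3. Replicate 1 on its own had 0 genes of either list, and replicate 2 on its own had 1 and 12. The comparison with 28 neuronal genes, of which 5 had regions in at least 2 replicates, did not pass (Fisher's exact test, adjusted p = 0.285). Those with astrocyte, ribosomal protein and endothelial, pericyte and meningeal genes did not pass either (Fisher's exact test, adjusted p = 0.639, 0.195 and 1). Unlike the comparisons with random lists, the Fisher's exact tests were not matched on gene length.

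The remaining lists did not differ from matched random lists in at least 2 replicates. Actin cytoskeleton and cell motility had 5 of 31 genes (expected 2.102, adjusted permutation p = 0.477), among them Actb, Cfl1 and Pfn1. The Pfn1 regions of replicates 2 and 3 did not overlap (chromosome 11, 70654280 to 70654597 and 70654981 to 70655254). Neurons had 5 of 28 (expected 1.88, adjusted permutation p = 0.3796), and opioid peptides, receptors and signalling had 3 of 25, the G protein genes Gnai1, Gnai2 and Gnao1 (expected 1.70, adjusted permutation p = 0.965). RUNX family and cofactors had 2 of 16 (Hdac1 and Kmt2a; expected 1.23, adjusted permutation p = 0.975), and astrocytes had 2 of 19 (Glul and Nfia; expected 1.19, adjusted permutation p = 0.975). Haematopoietic and lymphoid genes had 2 of 26 (Bach2 and Flt3; expected 1.52) and blood monocytes and neutrophils 1 of 19 (Mmp9; expected 0.953), each with an adjusted permutation p of 1. Cytokines and inflammatory signalling (24 genes), purinergic receptors and ATP release (21), endothelial cells, pericytes and meninges (22), mitosis and DNA replication (24) and olfactory receptors (17) had 0 genes each. Their expected counts were 1.22, 1.28, 1.43, 1.28 and 0.243. With so few genes expected, this measure could not show a list below random. Even 0 of 22 endothelial, pericyte and meningeal genes had a permutation p of 0.442.

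In replicate 3 on its own, 22 of 23 oligodendrocyte genes (95.7%; expected 8.01), 21 of 30 ribosomal protein genes (70.0%; expected 6.95) and 18 of 28 neuronal genes (64.3%; expected 10.7) had a region. Their adjusted permutation p-values were 0.0017, 0.0017 and 0.034. The neuronal result did not pass with genes assigned by RefSeq gene body (18 of 28, expected 12.4, adjusted permutation p = 0.112). Astrocyte genes had 7 of 19 (36.8%; expected 6.62, adjusted permutation p = 1). Endothelial, pericyte and meningeal genes had 0 of 22 (95% Wilson interval 0 to 14.9), fewer than the 7.82 expected (adjusted permutation p = 0.00227). Homeostatic microglial genes had 5 of 24, Mef2c, Sall1 and Sparc among them (20.8%; expected 7.36, adjusted permutation p = 0.532). The share of homeostatic microglial genes was lower than that of oligodendrocyte genes (Fisher's exact test, adjusted p = 1.23e-06), neuronal genes (Fisher's exact test, adjusted p = 0.00554) and ribosomal protein genes (Fisher's exact test, adjusted p = 0.00136). The comparison did not pass for astrocyte genes (Fisher's exact test, adjusted p = 0.392) or, where microglial genes had the higher share, for endothelial, pericyte and meningeal genes (Fisher's exact test, adjusted p = 0.100). These Fisher's exact tests were not matched on gene length either. RUNX family and cofactor genes had 12 of 16 (75.0%; 1.71 times the expected count) and microglial activation genes 3 of 26 (11.5%; below the 8.51 expected), neither of which passed (adjusted permutation p = 0.0674 for each). Microglial and macrophage transcription factors had 13 of 24 (54.2%; expected 8.69), which did not pass either (adjusted permutation p = 0.221).

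**Figure D3:**
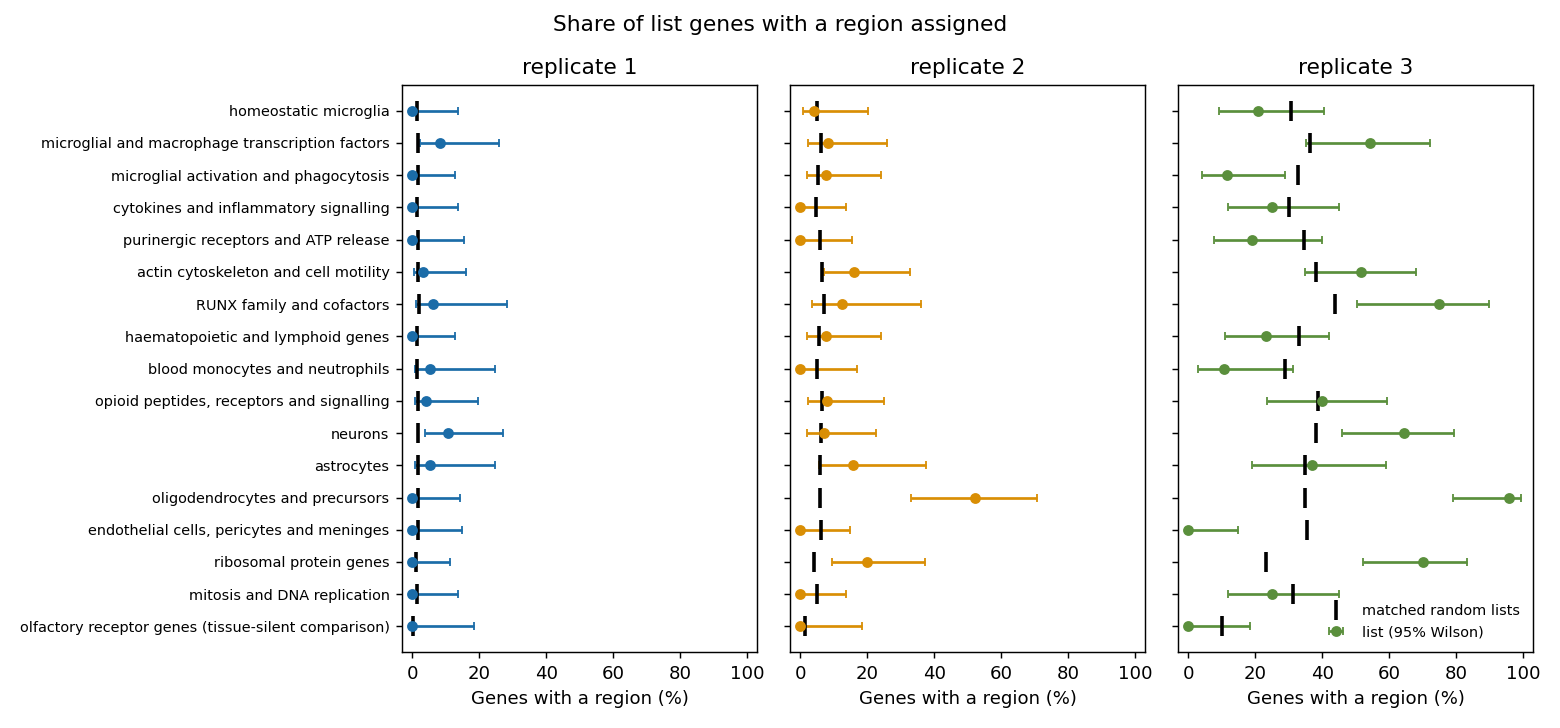
Each point is the share of a list's genes (%) with a region assigned by the authors in 1 replicate, with its 95% Wilson interval, and the black tick is the mean of random lists matched on gene length. In replicate 3, oligodendrocyte genes (95.7%) and ribosomal protein genes (70.0%) lay above their ticks and endothelial, pericyte and meningeal genes (0%) lay below.

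Runx1 itself and its partner had a region in replicate 3 alone. The Runx1 region lay in the promoter class on chromosome 16 (92696570 to 92696793, GRCm38), with a fold of 3.34, a pileup of 14 fragments and a rank at the 29.8 percentile of its list. Cbfb, which encodes the non-DNA-binding partner of RUNX proteins, had a promoter region on chromosome 8 (105170161 to 105170792) with a fold of 4.21 and a pileup of 35 fragments. The authors assigned 0 regions in the 3 replicates to Runx2 and Runx3, and 0 to the opioid receptor genes Oprm1, Oprd1, Oprk1 and Oprl1. With genes assigned by RefSeq gene body and 1 kb around it, Runx2 had a region in replicate 3. A gene without an assigned region was not shown to lack binding.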

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

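Gene assignment by RefSeq gene body, placement of promoter regions at gene ends and the p limit of replicate 1 were tests chosen after the data were seen. Every alternative for overlap had the smallest p possible, so the p could not rank them, but the shares moved: replicates 1 and 3 shared 94.7% of the regions of replicate 1, 68.5% by summits within 200 bp, 32.6% with 50% of both regions overlapping and 28.2% among the 451 regions of lowest q. At the p limit of replicate 1, replicates 2 and 3 kept 1392 and 10559 regions. With sharing defined by both other replicates, the difference in replicate 1 passed (log2 0.14 with 205 unshared regions, permutation p = 0.00077). The main definition gave a log2 difference of 0.10 with only 21 unshared regions, which limited that test. The cause of the change was not tested. Of the regions of replicate 1, 69.8% lay within 1 kb of either end of a RefSeq gene, a different quantity from the 82.7% in the authors' promoter class. The number of lists above random was 2, and it was 0 for all 3 replicates and for replicate 1 on its own, 1 without matching on length, 1 at a fold of 5 or more, 3 for any replicate and 3 for replicate 3 on its own. Leaving out each replicate in turn gave 0 to 2 such lists: 0 without replicate 2, 0 without replicate 3 and 2 without replicate 1. The number of lists below random was 0, and it was 1 for any replicate, 1 for replicate 3 on its own and 2 for RefSeq gene bodies in replicate 3. The main setting expected too few genes per list for a shortfall to pass. There, 0 of 22 endothelial, pericyte and meningeal genes against 1.43 expected had a permutation p of 0.442. The change in this number therefore does not show that a shortfall depends on the setting. With all 3 replicates, replicate 1 alone, or replicate 2 or 3 left out, the oligodendrocyte and ribosomal ratios to expectation were 0. Each of these settings required a region in replicate 1, which on its own had expected counts of 0.379 and 0.339. Without replicate 1 the ratios were 9.59 and 5.26, and for replicate 2 on its own they were 9.04 and 4.75. Blood monocyte and neutrophil genes fell to a ratio of 0.158 for RefSeq gene bodies in replicate 3 (adjusted permutation p = 0.0357). With the authors' assignment in replicate 3 the ratio was 0.366 (adjusted permutation p = 0.221). The cause was not tested. The alternative with all contigs removed no region and gave no value, and the motif alternatives were not run.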

Other observations

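The tests of cell type shares and constitutive promoters in replicate 3, the test of background steps and both alternatives for lysosomal folds were chosen after the results they bear on were seen, and the lysosomal list was written after the strongest regions were seen.

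Genes of lysosomal function carried Runx1 ChIP regions beyond the few among the strongest regions. Of 81 lysosomal genes that had not been seen before the list was written, 12 had regions in at least 2 replicates (14.8%, 95% Wilson interval 8.68 to 24.1) against 4.69 expected for genes of matched length. They included the proton pump genes Atp6v0a1, Atp6v0b, Atp6v0c and Atp6v0d1, the chloride transporter gene Clcn7, and Flcn, Gabarap and Lamtor1. Atp6v0b, Atp6v0d1, Clcn7, Gabarap and Lamtor1 had regions in all 3 replicates, against 0.717 genes expected (permutation p = 0.0028). Replicate 1 on its own had 8 of the 81 genes (expected 1.34, permutation p = 0.0006).

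For the strongest shared regions at lysosomal genes, a candidate explanation is that lysosomal genes are bound as a class. The 12 unseen genes exceeded matched random lists (two-sided permutation p = 0.0044), which went with that hypothesis. Ribosomal protein genes also exceeded them by this measure (6 genes against 1.26 expected), so an excess in at least 2 replicates was not particular to lysosomal genes. In replicate 1 on its own, 8 of the 81 unseen lysosomal genes had regions (expected 1.34), against 0 of 30 ribosomal protein genes. Only 0.339 ribosomal genes were expected there, so that 0 does not separate the classes. Signal at constitutive promoters remains open, since promoter regions of the unseen lysosomal genes in replicate 3 had a median fold of 4.08 over 57 regions against 3.84 over 8199 others (log2 difference 0.09, 95% bootstrap interval -0.06 to 0.51, permutation p = 0.221), and a p that misses the threshold does not show equal folds. The others held 10 regions of lysosomal genes seen before listing: without them the permutation p was 0.216, and with them counted as lysosomal the medians were 4.91 and 3.84 (permutation p = 1e-05), which decides nothing because those genes had been seen first. No biological contrast was available to separate the explanations.

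Replicate 3 had 29.3 times as many regions as replicate 1, and 22 of 23 oligodendrocyte genes against 0. The tables argue against lower depth of replicate 1 as the whole cause. With each pileup of replicate 3 at its lower 95% Poisson limit and scaled to the coverage of replicate 1, 3107 of its regions would still pass, against 451 called. The stricter p limit of replicate 1 left 10559 regions of replicate 3. Under the same limits the probability of 0 oligodendrocyte genes in replicate 1 was 2.74e-60, with 17.2 genes expected. A difference in enrichment or in the cells that entered the pools stays open and was not tested.

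In replicate 3, 22 of 23 oligodendrocyte and 5 of 24 homeostatic microglial genes had regions, though none of the 3 microglial lists differed from matched random genes. Regions in proportion to each cell type's share of the chromatin stay open as an explanation, as does signal at constitutive promoters. The values looked at were already known and support neither: endothelial, pericyte and meningeal genes had 0 regions among 22 genes (adjusted permutation p = 0.00227), and 70.0% of ribosomal protein genes had a region. Astrocyte genes had regions in 7 of 19 cases against 6.62 expected (adjusted permutation p = 1), and the share of each cell type in the pools is not known. Binding by Runx1 within oligodendrocytes was not tested, and no library without Runx1 was analysed here.

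The background levels implied by the deposited values may come from a scaled control library used in peak calling, which stays open because the steps were found in the same values. A total of 100% of the levels above the floor were multiples of 1 of 3 steps within 0.0001 in each replicate, where chance gives 1.87% to 2.23% for the finest step. That test allowed fractional fragment lengths, a form adopted after whole-number lengths had matched only 40.8% to 49.9% of the levels. The coarse steps were 0.386, 0.412 and 0.472 in replicates 1, 2 and 3. The finest steps alone held 55.8%, 61.4% and 51.4% of the levels. The middle step was set as a multiple of the finest step, so the match does not test it. The ratio of the steps implied fragment lengths of 232.5, 260.4 and 213.8 bp, and the narrowest regions were 232, 260 and 213 bp.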
